A study of Oryza sativa with 6 samples.

How the data were processed

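Grains of the rice wild type ZH11, a japonica cultivar, and of the drw1 mutant were collected 3 days after pollination, and total RNA was sequenced from 3 libraries per genotype, 6 in all. Per the labels, the grains came from field-grown plants and the libraries were made with an Illumina RNA library kit. The labels number the libraries of each genotype but do not say whether they came from separate plants, so p-values measure the spread between these libraries, which may be technical.

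The deposited table holds whole-number read counts per gene model, which the authors did not normalize, per the file headers and the values. Per the submitters' processing notes, fastp, HISAT2, featureCounts and DESeq were used, with no versions. The genome build, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads shared between near-identical copies, such as some members of the glutelin family of storage proteins, could therefore be divided or lost, and values of single members of such families are uncertain, as are those of overlapping and antisense genes. The deposited gene length of each model, in bases, was used only in a check for length bias.

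The columns of the wild type carry its name. The columns of the mutant carry another prefix than the label drw1, and were assigned to the drw1 libraries because the series holds no other genotype. The replicate numbers were taken from the column names. Every direction given for drw1 rests on this assignment. The mutated gene itself is not analysed here, because no source used here pairs it with a locus, so the labels were not checked against its expression.

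The table holds 39217 gene models, 38922 of them with a rice locus identifier and 295 with another identifier. No count was present in any library for 8418 models. Library totals were 19699620, 24147797 and 15582373 counts for ZH11 and 16440923, 16451196 and 17270099 for drw1. A gene without a read in one library lies below a floor of 3 counts, which is 0.131 to 0.201 CPM (counts scaled to a common library total by the TMM factors) in ZH11 libraries and 0.166 to 0.173 CPM in drw1 libraries. Over a whole genotype, the floor of 3 counts is 0.0534 CPM in ZH11 and 0.0567 CPM in drw1. Floors and 95% intervals (exact binomial) cover counting error only.

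Genotypes were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with genotype as the only factor, TMM scaling and edgeR's default filter on low counts. P-values were adjusted by the Benjamini-Hochberg method over the 23395 genes tested, with a threshold of 0.05. Log2 fold changes are drw1 over ZH11, and their standard errors were derived from the test statistic and are approximate. The test was first run on simulated counts for 23395 genes with the means and depths of these libraries. Of these genes, 200 were changed singly, and a further list of genes was lowered 2-fold. Among the 200, it recovered 62% of genes changed 1.5-fold, 86% at 2-fold, 96% at 4-fold and 98% at 8-fold. Of all its calls, 4.90% were unchanged genes. The lowered list was called, and of 8 unshifted gene lists in the simulation, 0 were called. The simulation drew genes independently and changed few of them, in random directions apart from the lowered list. It does not show these error rates for data in which most genes change or members of a list are correlated.

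Before the data were examined, 19 gene lists, the tests, the alternatives and a rule for naming single genes were fixed. The rule asked for annotated genes with the largest changes among those with a mean of at least 5 CPM in the higher genotype and no overlap between genotypes, and for up to 4 members of each list, and for at most 2 rising and 2 falling identifiers if no annotation paired identifiers with names. That case applied: the deposited table gives no names, and 0 of its identifiers are in the reference gene table (assembly ASM3414082v1). Single list members are therefore not named. The loci in 11 lists had been written down in advance from memory as 97 pairs of a gene symbol and a locus. For 44 of these symbols the reference gave a chromosome, and in 44 it was the chromosome of the locus. The pairs were not checked further and 53 symbols had no entry, so list membership is an assignment and not an annotation. The table holds 92 of these loci, and 89 were tested. The other 8 lists were defined only by words in gene descriptions and were not analysed here. They cover histones, cell cycle, transposons, photosynthesis, aleurone and transfer cells, heat shock, defence and ribosomal proteins. Most of the 11 analysed lists were also fixed to take in genes by such words, which could not be applied. These lists were tested on the loci written in advance alone and are narrower than fixed. The storage protein list lacks prolamins, and the embryo and auxin lists hold 2 loci each.

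Lists with at least 5 tested members were tested with camera of limma 3.58.1, with adjustment over the 9 lists. The correlation between genes was preset at 0.01, and estimated in a second run. With an estimate, camera also takes its degrees of freedom from the few libraries instead of the number of genes. That alone weakens a test. The share of called genes on each chromosome, read from the locus identifier, was compared with the rest by Fisher's exact test. Alternatives were DESeq2 size factors, library totals and upper-quartile factors as scaling, no filter and a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the edgeR likelihood-ratio test, thinning to the smallest library, a replicate block, the fry test of lists, and leaving out each library in turn. Libraries of one genotype differed by more than sampling noise (chi-square per gene 2.72 to 9.34), so no library was treated as a duplicate of another. Libraries prepared from 1 RNA would also differ by more than that, and the check does not show that they came from separate plants.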

Results

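RNA was measured in whole grains of wild-type ZH11 and the drw1 mutant, 3 libraries each, 3 days after pollination, to ask how the mutation changes gene expression in the young grain. Library totals ran from 15582373 to 24147797 counts. Across genes, log2 expression correlated at 0.988 to 0.991 between libraries of one genotype and at 0.868 to 0.874 between genotypes (genes are not independent replicates). The first principal component held 90.2% of the variance. The 10 most abundant genes took 2.86% to 3.17% of counts in ZH11 and 3.87% to 4.04% in drw1.

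Expression differed between genotypes across most of the transcriptome. Of 23395 genes tested, 16395 (70.1%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 8356 higher and 8039 lower in drw1. Changes of at least 2-fold were found in 6383 genes, 2972 higher and 3411 lower, and 418 genes rose and 425 fell by 8-fold or more. The libraries of the genotypes did not overlap in 16978 genes (72.6%), where chance gives 10%. The split between directions depended on scaling: 51.0% of calls were higher with TMM and 61.3% with library totals alone, which moved the median of all genes from 0.03 to 0.19 on the log2 scale (0.14 with upper-quartile factors). Among changes of at least 2-fold the larger direction turned, with 3700 higher and 2887 lower under library totals and 3466 and 3027 under upper-quartile factors. With a stricter filter on low counts, 4134 genes changed at least 2-fold, 1773 of them upward.

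**Figure D1:**
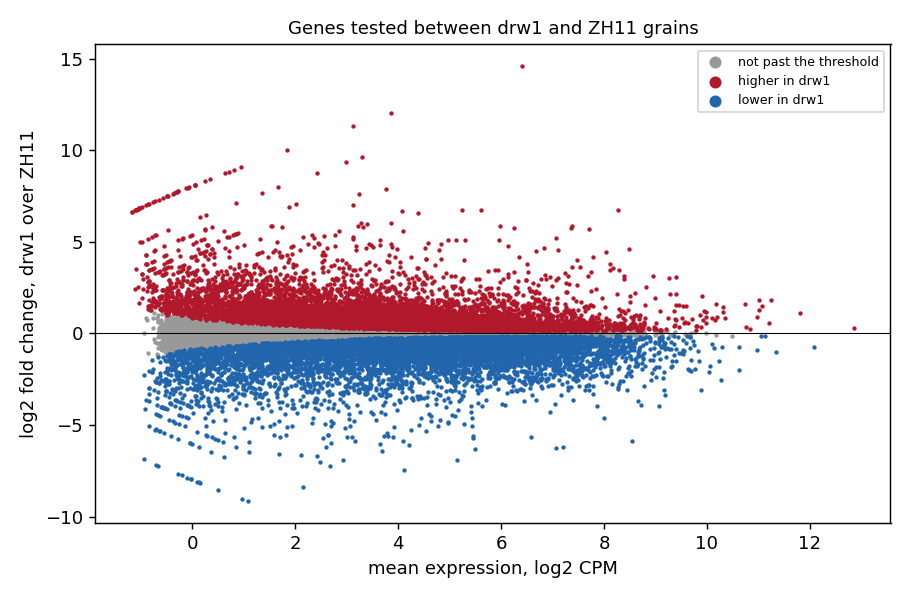
Log2 fold change of drw1 over ZH11 (y axis) against mean expression in log2 CPM (x axis), with 1 point per gene for 23395 genes. Red points (8356) were higher and blue points (8039) lower in drw1 at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and grey points did not pass; slanted rows of points are genes with almost no counts in a genotype, whose fitted values depend on the prior count.

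Loci assigned to seed storage proteins, the glutelins and the globulin that accumulate in endosperm, had the lowest median of the 11 lists. The lists were not tested against each other, and single loci elsewhere fell further. All 9 tested members were lower in drw1 by at least 2-fold, with a median log2 fold change of -5.45. The member with the largest fall went from 88.1 ± 11.2 CPM (SD, n = 3) in ZH11 to 1.09 ± 0.157 CPM in drw1, a log2 fold change of -6.32 (SE 0.15; edgeR quasi-likelihood test, adjusted p = 5.9e-16). Summed over the list, expression was 258 ± 8.52 CPM in ZH11 and 7.96 ± 0.517 CPM in drw1 (SD, n = 3). Adjusted over the list alone, 9 were lower. The list lay below other genes (camera, adjusted p = 2.0e-14, and adjusted p = 0.011 with an estimated correlation of -0.086). Some glutelin genes are close copies of each other and may share reads, which was not measured here, so values of single glutelin members are uncertain.

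Loci assigned to starch synthesis, the enzymes that make ADP-glucose and build starch from it and the transporter between them, were mostly lower in drw1. Of 24 tested members, 21 fell, 0 rose and 3 did not pass, and 13 fell at least 2-fold. Adjusted over the list alone, 21 were lower and 1 was higher. The median log2 fold change was -1.03. The largest fall was from 14933 counts over ZH11 to 182 over drw1, a log2 fold change of -6.26 (SE 0.10; edgeR quasi-likelihood test, adjusted p = 1.5e-17), and the smallest called fall was -0.35 (SE 0.09). Summed expression was 3805 ± 62.4 CPM in ZH11 and 1330 ± 30.6 CPM in drw1 (SD, n = 3). The camera test gave an adjusted p of 2.6e-16, and the call was lost at adjusted p = 0.062 with an estimated correlation of 0.175. The run with estimates also weakened the storage protein list, whose estimate of -0.086 lay below the preset 0.01. The lost starch call therefore cannot be put down to correlated members alone, since that run also has fewer degrees of freedom. With library totals or upper-quartile factors as scaling, 2 members were higher, and with library totals 20 were lower.

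Loci assigned to transcription factors of the endosperm and seed coat moved in both directions. Among 11 tested members, 8 fell, 6 of them at least 2-fold, and 3 rose, with the same counts adjusted over the list alone. The median log2 fold change was -1.61 and the largest fall was -6.66 (SE 0.39; 578 counts over ZH11 and 5 over drw1). The member with the largest rise had 0 counts over ZH11 and 38 over drw1, at least 13.5-fold higher against a floor of 3 counts over the genotype. The camera test gave an adjusted p of 0.0056, and the call was lost at adjusted p = 0.093 with an estimated correlation. That estimate was -3.5e-05, below the preset 0.01, so a higher correlation between members was not what weakened the call. The fewer degrees of freedom of that run were. With the stricter filter, 1 member was higher.

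Loci assigned to sucrose cleavage and sugar transport, which supply the grain with sugar, were split. All 9 passed the test, 4 higher and 5 lower (median -0.55), also adjusted over the list alone, and the list as a whole did not stand apart (camera, adjusted p = 0.30). The largest fall was from 58956 to 5480 counts, a log2 fold change of -3.35 (SE 0.06), and the largest rise was 1.71 (SE 0.09; edgeR quasi-likelihood test, adjusted p = 1.7e-11). Of 8 tested grain size loci, 6 rose and 2 fell, also adjusted over the list alone, with a median log2 fold change of 0.70 (camera, adjusted p = 0.42). The largest rise among these had 1 count over ZH11 and 117 over drw1, a ratio of 124 with a 95% counting interval of 21.9 to 4952.

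Of 7 loci assigned to DNA replication, 6 fell and 1 rose, also adjusted over the list alone, with a median log2 fold change of -0.81. The largest fall was -1.18 (SE 0.13) and the rise was 0.80 (SE 0.08; edgeR quasi-likelihood test, adjusted p = 5.7e-08). With library totals or upper-quartile factors, and without ZH11 replicate 2 or drw1 replicate 3, 5 were lower. The list did not pass the camera test (adjusted p = 0.30). Among 6 loci assigned to DNA damage response and repair, 2 fell, also adjusted over the list alone, 0 rose and 4 did not pass (camera, adjusted p = 0.53).

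Among 6 loci assigned to Polycomb complexes, which silence genes through histone methylation, 3 fell, 1 rose and 2 did not pass. Adjusted over the list alone, 4 were lower and 1 was higher. The largest fall was -2.83 (SE 0.12; edgeR quasi-likelihood test, adjusted p = 9.6e-13). The rise was small, 0.17 (SE 0.07; edgeR quasi-likelihood test, adjusted p = 0.033), and its call was lost in 9 of 16 alternatives, 5 of them among the 6 that leave out a library. Over these alternatives its adjusted p (edgeR, DESeq2 or limma) ran from 0.00038 to 0.13. With DESeq2 size factors 4 members were lower. Among 7 loci of DNA methylation and demethylation, 4 fell and 1 rose, also adjusted over the list alone, and the median of -0.19 was -0.03 with library totals alone. Their largest fall was -1.20 (SE 0.16). The rise lost its call in 6 of 16 alternatives, 4 of them among the 6 that leave out a library. The smallest fall (-0.19, SE 0.07) lost its call with library totals or upper-quartile factors and without drw1 replicate 2 or 3, which leaves 3 lower. Neither list passed camera (adjusted p = 0.30 and 0.42).

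The remaining lists, filled by loci alone and not by gene descriptions, had too few tested members for a list test. The single embryo marker tested had a log2 fold change of -0.11, which was not past the threshold (SE 0.16; edgeR quasi-likelihood test, adjusted p = 0.52) and was 0.04 with library totals alone, and another had 18 counts over ZH11 and 7 over drw1. The single auxin synthesis locus tested fell by 2.02 on the log2 scale (SE 0.20; edgeR quasi-likelihood test, adjusted p = 1.0e-07), and another had 18 counts over ZH11 and 0 over drw1.

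**Figure D2:**
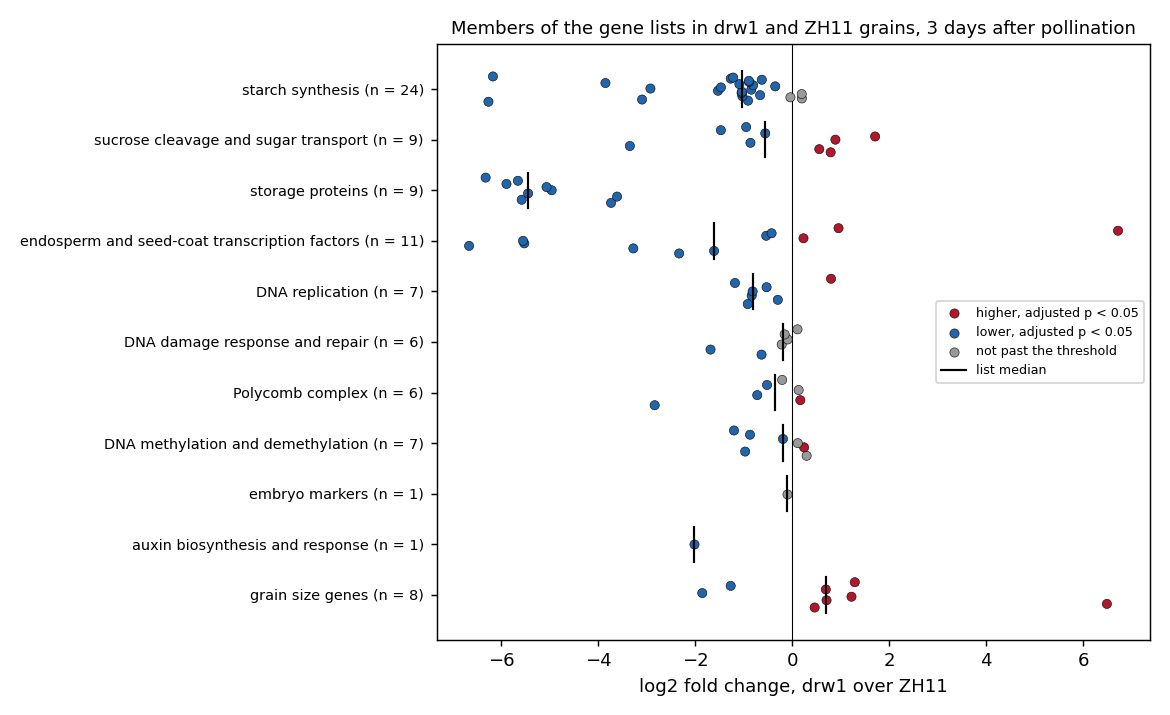
Log2 fold change of drw1 over ZH11 (x axis) for each tested member of the 11 gene lists (y axis), 1 point per locus, with a vertical bar at the list median. Red points were higher and blue points lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and all 9 storage protein points lie below 0; fitted values of loci with 0 or 1 count in a genotype depend on the prior count.

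**Figure D3:**
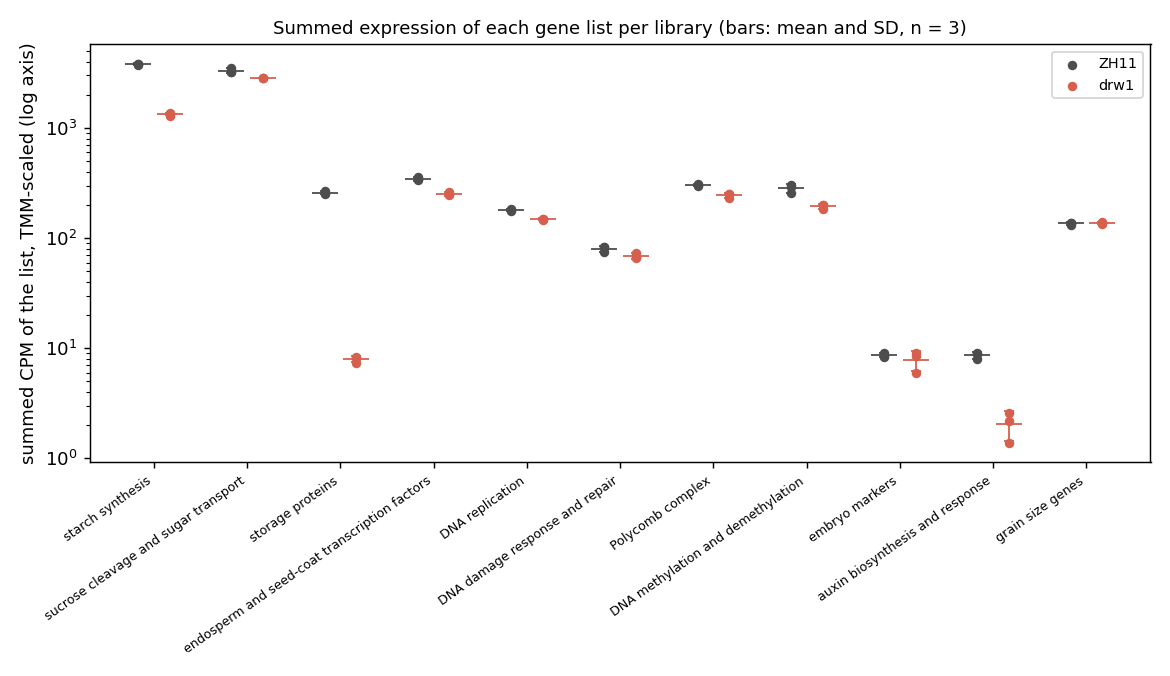
Summed CPM (y axis, log scale) of each gene list (x axis) in each library, with 1 point per library and bars for the mean and SD of 3 libraries. Storage protein loci summed to 258 CPM in ZH11 and 7.96 CPM in drw1, and grain size loci to 136 and 138 CPM.

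By the fixed rule, the 2 largest rises and 2 largest falls were taken among genes with at least 5 CPM in the higher genotype and no overlap between genotypes; loci under 5 CPM can have larger fitted changes. LOC_Os03g02470 had 0 counts over ZH11 and 170 ± 2.02 CPM in drw1 (SD, n = 3), at least 3182-fold higher against the floor of 3 counts over the genotype. LOC_Os11g10514 had 0 counts over ZH11 and 29.1 ± 1.78 CPM in drw1 (SD, n = 3), at least 544-fold higher. LOC_Os07g11360 had 478 counts over ZH11 and 1 over drw1, a ratio of 450 with a 95% counting interval of 80.4 to 17806. LOC_Os07g05940 went from 33.7 ± 1.12 CPM in ZH11 to 0.188 ± 0.174 CPM in drw1 (SD, n = 3), a log2 fold change of -7.43 (SE 0.24; edgeR quasi-likelihood test, adjusted p = 2.8e-14).

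Calls were spread over all 12 chromosomes, at 68.2% to 71.8% of tested genes each. No chromosome differed from the rest in Fisher's exact test (0 at an adjusted p and 0 at an unadjusted p under 0.05). Counting changes of at least 2-fold, 2 chromosomes differed. Chromosome 11 had 31.4% of genes called against 27.1% elsewhere (Fisher's exact test, adjusted p = 0.0087). Chromosome 3 had 25.1% against 27.6% (Fisher's exact test, adjusted p = 0.018). These tests treat genes as independent, so neighbours that change together make the p-values too small.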

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

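The count of changed genes ran from 15243 to 16522 when 1 library was left out and was 15893 with DESeq2 and 16436 with limma-voom, and 0 genes were called in the opposite direction under any alternative. The replicate number as a block called 15505 genes, 15485 of them shared. The labels tie no number to a shared plant or day, and same-numbered libraries deviated with correlations of -0.12, 0.02 and -0.10, and 1 of 6 libraries correlated best with its own number. The stricter filter, which tests fewer genes, gave 4134 genes changed at least 2-fold and 1773 higher. Counts of list members under each alternative were chosen after seeing the data. Polycomb members higher numbered 0 with DESeq2 size factors, DESeq2, the block (in which no list test changed) and thinning, 2 with library totals and upper-quartile factors, and 0 to 1 without 1 library. DNA methylation members higher numbered 0 with DESeq2 size factors and DESeq2, and 0 to 1 without 1 library. Starch members higher numbered 2 with library totals and upper-quartile factors, 1 with no filter, the stricter filter and limma-voom, and 0 to 1 without 1 library. Auxin members lower numbered 2 with no filter and DESeq2, and transcription factors higher numbered 1 with the stricter filter. The cause of these shifts was not tested. With an estimated correlation the camera adjusted p was 0.062 for starch and 0.093 for transcription factors. The fry test, which asks whether a list moves and not whether it differs from other genes, gave adjusted p of 0.000342 for sucrose, 0.000212 for replication, 0.00275 for damage response, 0.000342 for Polycomb, 0.00709 for DNA methylation and 0.00269 for grain size. With 2-fold calls only, 2 chromosomes differed. For the 40 loci taken by the fixed rule, 625 alternative values kept their side of the threshold, 13 lost it and 0 reversed. A change of sign was counted as a reversal only for loci past the threshold in the main test. The embryo marker, which was not past it, changed sign with library totals (0.04).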

Other observations

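The tests of a single share of endosperm, of a single share of the remaining tissue, of stretches of loci and of chromosome 5 were chosen only after the results were seen, as were the bootstrap intervals.

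Strongly lowered loci lay close together on chromosome 7. In a run of 51 neighbouring tested loci, in the order of their identifiers and including LOC_Os07g11360, the mean log2 fold change was -1.67, with 29 loci lower, 20 of them at least 2-fold, 13 higher and 9 not past the threshold. The mean was carried by 14 loci that fell 8-fold or more. The other 37 had a mean of -0.07 and a median of 0.06. Fitted values of loci with almost no counts in drw1 depend on the prior count. The lowest mean of any such run in 1000 shuffles of the gene order was -1.01 (one-sided permutation p = 0.000999, the smallest these shuffles can give). The highest run, on chromosome 4, had a mean of 0.83 (one-sided permutation p = 0.056). The length of the run was set after the data were seen, and neighbouring copies of one family can share reads. The loci of the run have no names here. Whether they belong to 1 family that fell as a set, such as storage proteins, was not checked. A shuffle of gene order cannot tell such a family from an effect of position.

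Some loci were read in only 1 genotype. With at most 3 counts over the other genotype and at least 1 CPM, 57 loci were read in drw1 and 53 in ZH11. Of the 53, 13 lay on chromosome 5, where 4.43 would fall by the share of tested genes (Fisher's exact test, adjusted p = 0.0079 over 24 tests). No other of the 24 tests passed. Fisher's test treats loci as independent, and whether the 13 lay side by side was not tested.

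All 9 storage protein loci and 21 of 24 starch loci were lower in drw1, though the starch list lost its call with an estimated correlation (camera, adjusted p = 0.062). For the lists pooled, the tables argue against gene length or abundance bias as the whole cause. The 33 members lay below the 200 genes nearest in length by a median of -1.25 log2 (95% bootstrap interval -3.76 to -0.82). They lay below those nearest in abundance by -1.12 (-3.69 to -0.96). Both intervals reach above the bound of -1 set in advance and exclude the -0.5 that a bias allowed. The bootstrap drew members as independent, which correlated members are not. The starch list was not matched on its own, so these values do not settle the question for it. A smaller share of endosperm in the drw1 grain may contribute, and cannot be told apart from lower expression per cell. For the test of a single share, 16 loci assigned to endosperm were used. They were picked by gene symbol as restricted to the endosperm, after the results were seen. The set held the 9 storage protein loci and the Polycomb locus that had the largest fall. It also held 6 transcription factor loci, which are those that fell at least 2-fold. The other transcription factor loci, of which 3 rose, were left out. Log2 fold changes of the 16 loci ran from -1.61 to -6.66. Their SD was 7.08 times the median standard error, which exceeds the bound of 3 first set against a single share. That bound was replaced after the value was seen, because low expression in other tissues would spread the loci too. The rule that replaced it asked whether any of the 16 loci rose. The 3 risen transcription factor loci were not among them, so the test decides nothing. A delay of grain development and an effect of the mutation on these genes stay open and were not tested.

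The 57 loci with almost no counts in ZH11 may differ between the lines themselves. A larger share of all remaining grain tissue would raise many genes alike, and 0.496% of tested genes rose at least 32-fold. A tissue that already makes up much of the grain cannot rise 32-fold in share. The value was therefore bound to be low and decides nothing about a changed share of tissue, and a rare tissue also stays open. Linked segments of another background would put such loci side by side, and 10.5% lay within 10 tested loci of another. The median was 8.77% for strongly risen genes with counts in both genotypes (one-sided permutation p = 0.490). It was 3.51% for random tested genes (one-sided permutation p = 0.137). Strongly risen genes could themselves lie in such segments, and the 53 loci read in ZH11 were not tested this way, which leaves that explanation open. Sequence differences between the lines and the reference were not tested.

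The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 16395 genes, 6383 genes with a 2-fold change, 3 lists and 0 chromosomes. The highest of the other splits gave 0 genes, 0 genes with a 2-fold change, 2 lists and 0 chromosomes. Each of these splits mixes the genotypes within its groups and unequally between them. The genotype difference then adds to the spread within groups, so few genes could be called, and the splits give no null for genes or lists. A value as large came from 1, 1, 1 and 10 of the 10 splits, the real one included.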
